A study of Mus musculus with 20 samples.

How the data were processed

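The series held 20 RNA sequencing libraries of mouse cells, made from mRNA purified on beads. One table held a differentiation time course of 12 libraries and the other a survey of 8 libraries from stem cell and fibroblast lines, called the discovery set here. Per the labels, the time course used E14 embryonic stem cells carrying lentiviral short hairpin RNAs, selected with puromycin, that were differentiated towards heart muscle and sampled at days 0, 3, 6 and 9. The labels describe both an embryoid body protocol and a directed cardiomyocyte protocol for each of these samples, and which was used for a library is not given in the sources used here. There were 3 cultures (a scrambled hairpin and hairpins A and B against Braveheart), each with 1 library per day. Hairpins A and B were taken as the 2 replicates of the depleted group.

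The time course values are FPKM per gene, made by the authors with TopHat 1.14, Bowtie 0.12.7 and Cufflinks 1.3.0 on the mouse genome build mm9, per the submitters' processing notes. The table had 22102 entries, and 595 loci shared a gene name with another locus and were kept apart. Per the file headers each value carried a quantification status, which was "ok" for 260680 of 265224 values, "lowdata" for 3968 and "fail" for 576. The 16 columns of lower and upper bounds of the FPKM were not used here. The authors also deposited 8 columns of ratio values between libraries, and these equalled the ratio of (FPKM + 1) with a largest relative difference of 1.42e-06. Spreadsheet software had turned 25 gene names into dates, and those entries were not named here.

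The discovery values are expected counts and TPM per gene, made by the authors with TopHat 1.3 and RSEM on mm9, per the submitters' processing notes; the annotation version is not given in the sources used here. The table had 42458 entries, of which 343 held no values. Of the deposited expected counts, 58.0% were whole numbers to within 1e-09 reads. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense genes cannot be separated. Genes with near-identical copies are uncertain, since the authors' counting can split reads among copies.

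Counts and depth were read from the tables. The total of the expected counts ran from 7536503 to 23662593 reads per discovery library. The time course table gave no counts, and the size of the smallest FPKM steps implied, in units of 1e+06 reads, between 6.73 and 10.99 per library. A value of 3 reads on a gene of 1 kb then corresponded to between 0.273 and 0.446 FPKM. In the discovery set 3 reads corresponded to between 0.132 and 0.431 counts per 1e+06 reads (CPM). These floors cover counting error only.

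Before the data were examined, both tables were assumed to hold RPKM values, to be tested with limma. The time course was tested that way, with limma 3.58.1 in R 4.3.3 (moderated by eBayes with a mean trend) on log2(FPKM + 1). Genes with at least 1 FPKM in at least 2 libraries were kept, which left 14108. The discovery table held expected counts, so its main test became edgeR's quasi-likelihood test (edgeR 4.0.16, TMM scaling) on expected counts rounded to whole numbers. Genes with at least 1 CPM in at least 2 libraries were kept, which left 16773. All p-values were two-sided, adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Folds in FPKM are on the log2(FPKM + 1) scale, which understates the change of low genes.

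The effect of depletion at each day was the mean of both hairpin libraries minus the scrambled library of that day, in 1 fit of the 12 libraries with 8 groups. The fit had 4 residual degrees of freedom, all from pairs of hairpin libraries, and the lone scrambled library of a day was assumed to vary like them. The mean effect over the days and the day 9 effect minus the day 0 effect came from the same fit. The course of differentiation compared each later day with day 0 over the 3 cultures, with depletion as a covariate and 7 residual degrees of freedom. A count of genes at least 2-fold from the scrambled library in the same direction in both hairpins was made without a p-value, and again with each hairpin culture taken as the odd library. The discovery fit had 5 groups and 3 residual degrees of freedom, and its 5 comparisons were mESC against MEF, mESC against partially reprogrammed, miPS against mESC, partially reprogrammed against MEF, and E14 against v6.5.

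The libraries of a culture follow 1 cell line through the days, so culture pairs the time course libraries. As a check, the correlation of deviations from the day means between libraries of a culture ran from -0.0910 to 0.642, and was 0.447, 0.339 and 0.642 between days 6 and 9 of the scrambled, hairpin A and hairpin B cultures. The fits with culture as a block are given beside the counts they move.

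Before the data were examined, 24 gene lists were fixed. They covered pluripotency, primitive streak and nascent mesoderm, cardiac mesoderm and progenitor regulators, cardiomyocyte structure and contraction, epithelial to mesenchymal transition, epithelial, endothelial, blood, smooth muscle, skeletal muscle, neural, endoderm, fibroblast and extracellular matrix, proliferation, polycomb and DNA methylation, interferon response, p53 targets, amino acid and ER stress, hypoxia and glycolysis, BMP and TGFb targets, Wnt targets, neighbours of the Braveheart locus, long noncoding and imprinted RNA, and reprogramming factors. Lists were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, and with fry, adjusted over the lists of a comparison. A list needed 5 measured members, so the reprogramming factors, with 4, were described by gene only, and skeletal muscle was tested in the time course alone.

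The genes named were set by a rule fixed before the data were examined. It took the 8 largest rises and 8 largest falls past the threshold in each comparison (for depletion, with the same sign in both hairpins), leaving out predicted models. It added up to 4 members of each list with the largest changes, and a fixed set of lineage genes. Genes outside that rule are said to have been chosen after their values were seen.

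The alternatives tried were a pseudocount of 0.1, no filter on low values, median-ratio rescaling, a block for the culture or the replicate number, leaving out each replicate, and a 4-fold size rule. Others were chosen after seeing the data: leaving out loci under 300 bp, DESeq2 1.42.0, limma on log2(TPM + 1), leaving out fibroblast genes, the library set as a term, 1 library set alone, and offsets for transcript GC content and length (from the longest GENCODE mouse transcript of each gene, matched by identifier). For the discovery comparisons, a fold against a group with 0 counts was set against a floor of 3 counts in each library. Scripts in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3) and R were tested on simulated data with 200 genes changed by known amounts. For depletion at day 9 (14108 genes), planted log2 changes of 1, 2 and 4 were recovered in 4.48%, 38.8% and 86.4% of genes, with 7 false calls. For day 9 against day 0, the shares were 49.3%, 88.1% and 98.5%, with 12 false calls. For mESC against MEF (16046 genes), the shares were 0%, 1.49% and 72.7%, with 4 false calls.

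Braveheart itself was looked up by its known names and no entry carried one, and unnamed entries near its neighbours were not assigned to it, since the sources used here give no mm9 coordinates for it, so the level of the targeted RNA was not analysed here and the hairpin labels could not be checked against it.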

Results

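Gene expression was measured by RNA sequencing in 20 mouse libraries, to ask what changes when Braveheart, a long noncoding RNA, is depleted while embryonic stem cells differentiate towards heart muscle. The first set was a time course of 12 libraries from E14 embryonic stem cells. It had a culture with a scrambled short hairpin RNA, a culture with hairpin A and a culture with hairpin B against Braveheart, each sampled once at days 0, 3, 6 and 9. The second set surveyed 8 libraries from lines that were used to pick candidate noncoding RNAs. These were mouse embryonic stem cells (mESC) of the lines E14 and v6.5 (2 libraries each), embryonic fibroblasts (MEF, 1 library), fibroblasts partially reprogrammed with retroviral Oct4, Sox2, c-myc and Klf4 (2 lines, 1 library each), and a fully reprogrammed induced pluripotent line (miPS, 1 library). The low values of the time course implied depths, in units of 1e+06 reads, of 9.77, 10.0, 8.31 and 8.78 at days 0, 3, 6 and 9 of the scrambled culture. Hairpin A gave 7.85, 9.41, 7.17 and 6.73 in the same units, and hairpin B 10.1, 10.0, 10.2 and 10.99. The discovery libraries summed to 17008367 and 23662593 reads for E14, 7815744 and 12389911 for v6.5, 8762640 for MEF, 7536503 and 7553667 for the partially reprogrammed lines, and 7613843 for miPS. Nothing in the labels says that replicates were separate cultures, and hairpins A and B differ in sequence, so p-values measure only the spread between these samples. The level of Braveheart, the target of both hairpins, was not analysed here.

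At day 9 the genes of the heart muscle contractile apparatus were lower in both hairpin cultures than in the scrambled culture. Actc1, cardiac alpha actin (chromosome 2, 113873024 to 113878547 in mm9), stood at 140 FPKM in the scrambled library, 15.4 with hairpin A and 4.30 with hairpin B, a log2 difference of -3.92 ± 0.77 (SE). The troponin genes Tnni1 and Tnnt2, which control thin filament contraction, read 53.9, 7.48 and 1.41 FPKM and 55.5, 9.40 and 1.29 FPKM in the same order. The atrial light chain Myl7 read 138, 33.7 and 3.14 FPKM and the cardiac myosin heavy chain Myh6 31.1, 4.23 and 1.02 FPKM. These single genes did not pass limma's adjusted threshold (adjusted p = 0.873 for each). The spread in that fit came from the hairpin pairs of all days, which lay far apart at days 6 and 9. Failing to pass therefore does not show that these genes were unchanged. Of the 22 cardiomyocyte genes measured, 19 were lower in both hairpins, with a median log2 difference of -1.61 (-1.42 for hairpin A alone and -2.10 for hairpin B alone). The list was lower than other genes by camera (adjusted p = 1.22e-14) but not with an estimated correlation (adjusted p = 0.0666 with an estimated correlation). By fry, which tests the list's own genes without comparing them with other genes, it was lower with depletion (adjusted p = 0.0148). None of its genes passed over all genes tested, against 8 that fell when adjusted over the list alone. Its day 9 effect also lay below its day 0 effect, with a median of -1.63 and a camera adjusted p of 2.83e-11 (adjusted p = 0.108 with an estimated correlation).

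Regulators of heart progenitors were lower with both hairpins from day 6. Hand2 and Hand1, transcription factors of the forming ventricles, read 9.42, 1.62 and 0.0378 FPKM and 24.9, 7.43 and 1.81 FPKM at day 6 in the scrambled, hairpin A and hairpin B libraries, log2 differences of -2.66 ± 0.72 (SE) and -2.41 ± 0.72 (SE). The VEGF receptor Kdr, present on early cardiac and vascular progenitors, read 14.1, 3.03 and 1.03 FPKM and the PDGF receptor Pdgfra 8.87, 3.00 and 0.399 FPKM. Mesp1, a master regulator of cardiac mesoderm, read 2.82 and 1.13 FPKM in the scrambled and hairpin A libraries and was listed at 0 with hairpin B. Gata4 read 12.9, 8.097 and 1.75 FPKM, Nkx2-5 3.16, 1.33 and 0.407 FPKM, and Isl1 15.4, 12.4 and 1.16 FPKM. None of these genes passed alone (limma, adjusted p = 1). Of the 17 cardiac mesoderm and progenitor regulators, 16 were lower in both hairpins at day 6, with a median of -1.42 (-0.84 for hairpin A and -1.95 for hairpin B). Camera gave an adjusted p of 7.24e-18 (adjusted p = 0.223 with an estimated correlation). At day 9, 14 of them were lower in both hairpins, with a median of -1.05 and an adjusted p of 3.42e-05 (adjusted p = 0.516 with an estimated correlation). There Gata4 read 6.65, 3.65 and 1.54 FPKM and Isl1 9.40, 5.87 and 0.738 FPKM, while Hand1 read 6.23, 4.40 and 11.3 FPKM.

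**Figure D1:**
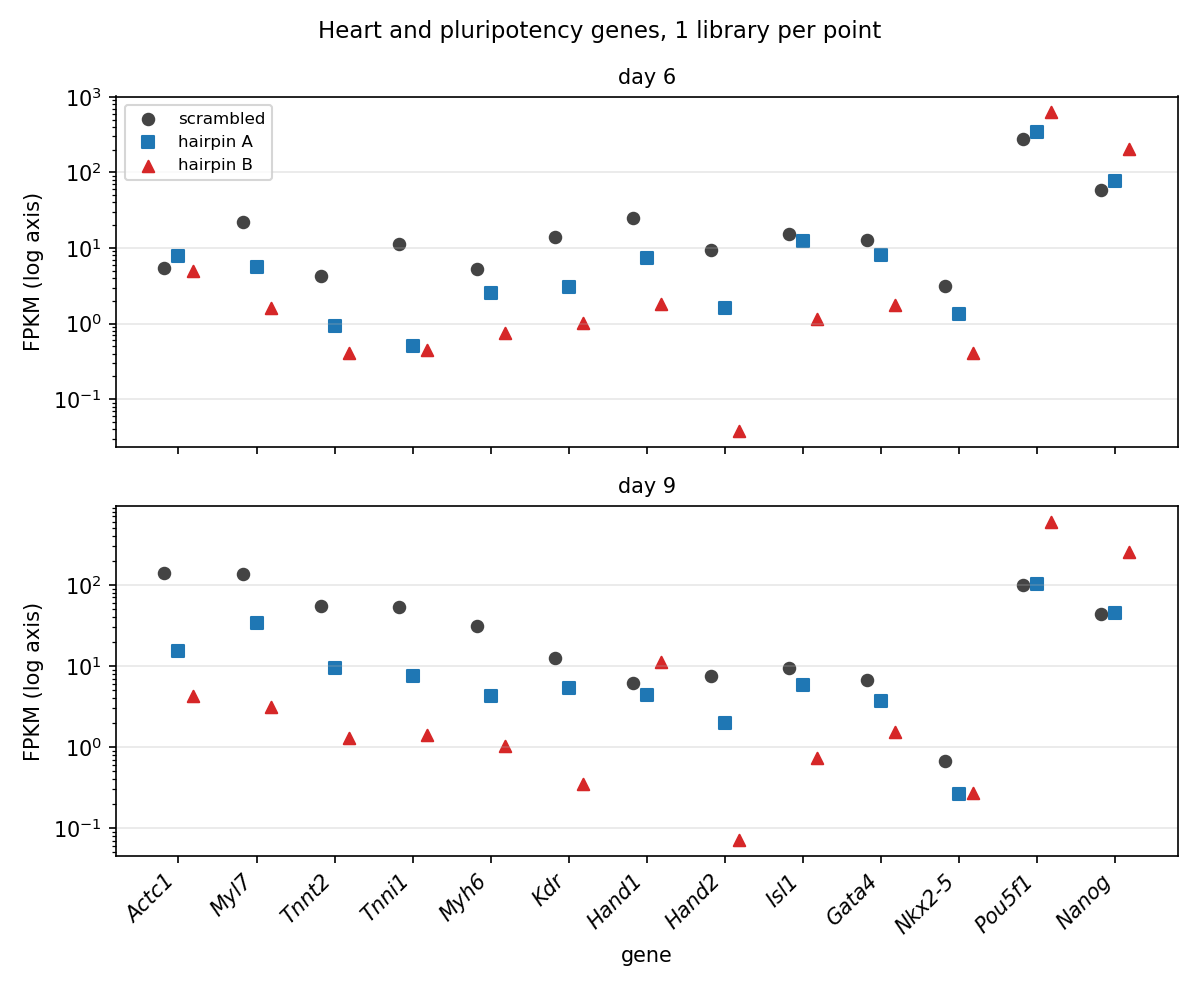
FPKM (log axis) of heart and pluripotency genes in each of the 3 cultures at day 6 (top) and day 9 (bottom), 1 library per point, with no error bars because each point is a single library. At day 9 the contractile genes from Actc1 (140, 15.4 and 4.30 FPKM) to Myh6 (31.1, 4.23 and 1.02 FPKM) are ordered scrambled, hairpin A, hairpin B, and Pou5f1 is highest in hairpin B at 602 FPKM.

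Most members of the blood, endothelial and mesenchymal transition lists were also below scrambled in both hairpins, although none passed alone. The embryonic globin Hbb-bh1 read 426, 93.6 and 0.944 FPKM and Hba-x 103, 17.2 and 0.389 FPKM in the scrambled, hairpin A and hairpin B libraries of day 6. Of the 14 blood genes, 13 were lower in both hairpins at day 6, with a median of -1.90 (-1.31 in hairpin A and -2.46 in hairpin B) and a camera adjusted p of 8.44e-17 (adjusted p = 0.223 with an estimated correlation). At day 9 the count was 10 of 14, with a median of -1.12 (-0.68 in hairpin A and -1.56 in hairpin B) and an adjusted p of 0.000108 (adjusted p = 0.516 with an estimated correlation), and Hbb-y read 31.2 and 7.71 FPKM and was listed at 0 with hairpin B. Of 16 epithelial to mesenchymal transition genes, 13 were lower in both hairpins at day 6 and 13 at day 9, with medians of -1.004 and -1.14 (camera adjusted p = 2.73e-08 and 2.08e-05, and adjusted p = 0.306 and 0.516 with an estimated correlation). The medians in hairpin A alone were -0.37 and -0.46 and those in hairpin B -1.54 and -1.77. Within that list Twist1 read 26.4, 16.0 and 3.85 FPKM and Snai1, a repressor of epithelial adhesion, 7.90, 5.48 and 3.36 FPKM at day 9. Of 15 endothelial genes, 9 were lower in both hairpins at each of these days, with medians of -0.84 and -0.99 (camera adjusted p = 4.37e-05 and 3.42e-05, and adjusted p = 0.176 and 0.166 with an estimated correlation). These medians were -0.62 and -0.52 in hairpin A and -1.01 and -1.46 in hairpin B. The fetal liver and yolk sac gene Afp read 21.1, 9.78 and 0.379 FPKM at day 9. The endoderm list had medians of -0.72 at day 6 and -0.91 at day 9 (camera adjusted p = 0.000341 and 0.00574, and adjusted p = 0.509 and 0.566 with an estimated correlation), but 0.04 and -0.06 in hairpin A alone. Without the hairpin B library camera did not call endoderm at day 9 (adjusted p = 0.623). Fibroblast and extracellular matrix genes had a median of -0.61 at day 9, with 15 of 20 lower in both hairpins (camera adjusted p = 0.000108, and adjusted p = 0.516 with an estimated correlation). Their mean was -0.85, and -0.48 without the hairpin B library.

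Pluripotency genes were higher in the depleted group at days 6 and 9, and nearly all of that difference lay in hairpin B. At day 9 Pou5f1 (Oct4) read 98.8, 102 and 602 FPKM and Nanog 44.3, 45.4 and 256 FPKM in the scrambled, hairpin A and hairpin B libraries. The median of the 20 pluripotency genes was 3.00 above scrambled on the log2 scale with hairpin B and 0.218 with hairpin A. Of these genes, 17 were higher in both hairpins at day 9 and 14 at day 6, so the small difference in hairpin A mostly had the same direction. The list median of the group was 1.60 at day 9 and 1.27 at day 6 (camera adjusted p = 3.57e-08 and 1.07e-06, and adjusted p = 0.516 and 0.423 with an estimated correlation). At day 0, Pou5f1 read 604, 689 and 682 FPKM, and Nanog 201, 205 and 175 FPKM. Without the hairpin B library camera did not call the list at day 6 but still called it at day 9. Those fits set a lone hairpin A library against the lone scrambled library of the day. The list median in hairpin A was 0.289 at day 6 and 0.218 at day 9. The hairpin B libraries of days 6 and 9 stood apart from those of the other cultures on the same days. Across genes, the day 9 library of hairpin B correlated at 0.944 to 0.953 with the day 0 libraries and at 0.934 to 0.936 with those of day 3, and its day 6 library at 0.934 to 0.945 with day 0 and 0.947 to 0.954 with day 3. On the first principal component, with 44.0% of the variance, day 0 lay between -43.8 and -40.6 and day 3 between -33.1 and -22.7. The day 9 libraries of the scrambled, hairpin A and hairpin B cultures lay at 79.9, 73.6 and -29.3 there, and the day 6 library of hairpin B at -13.5. On the second component, with 15.1%, the day 9 library of hairpin B lay at 26.6, day 0 between 20.4 and 33.8 and day 3 between -38.7 and -33.5. Across the 14108 genes, which are not independent replicates, the change from day 0 to day 9 correlated at 0.781 between hairpin A and scrambled and at 0.171 between hairpins A and B. The lower heart, blood and vascular values of hairpin B above therefore stand beside that position of its libraries.

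**Figure D2:**
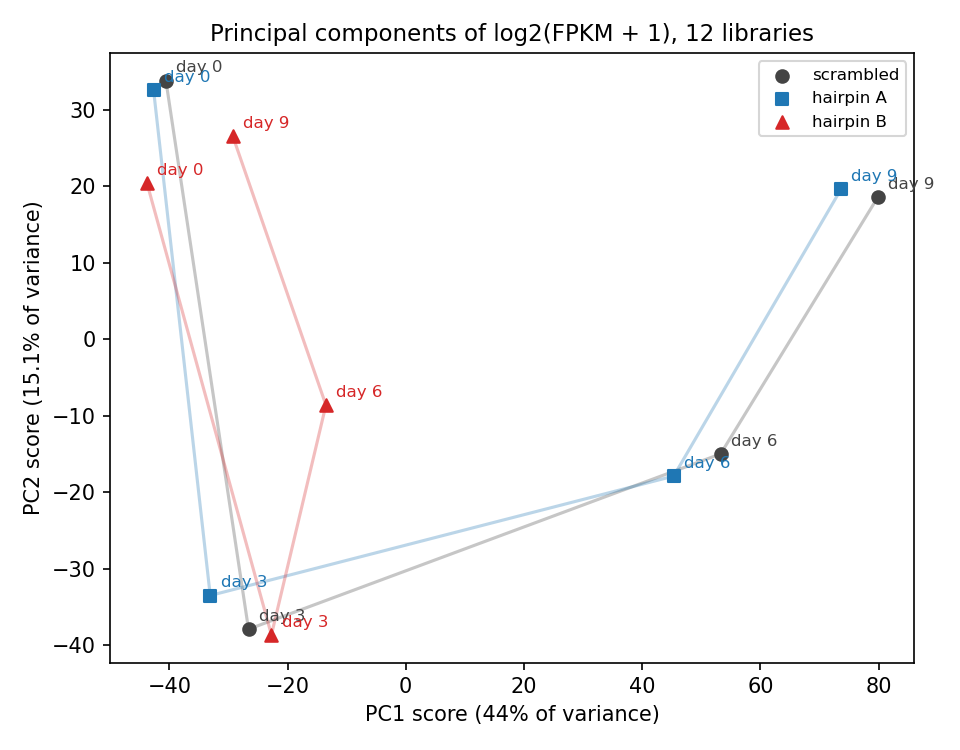
Scores of the 12 time course libraries on the first principal components of log2(FPKM + 1), with the share of variance on each axis and lines joining the days of a culture. The scrambled and hairpin A libraries move to 79.9 and 73.6 on the first component by day 9, and hairpin B lies at -29.3, within the range of day 3 on that component and of day 0 on the second (26.6).

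**Figure D3:**
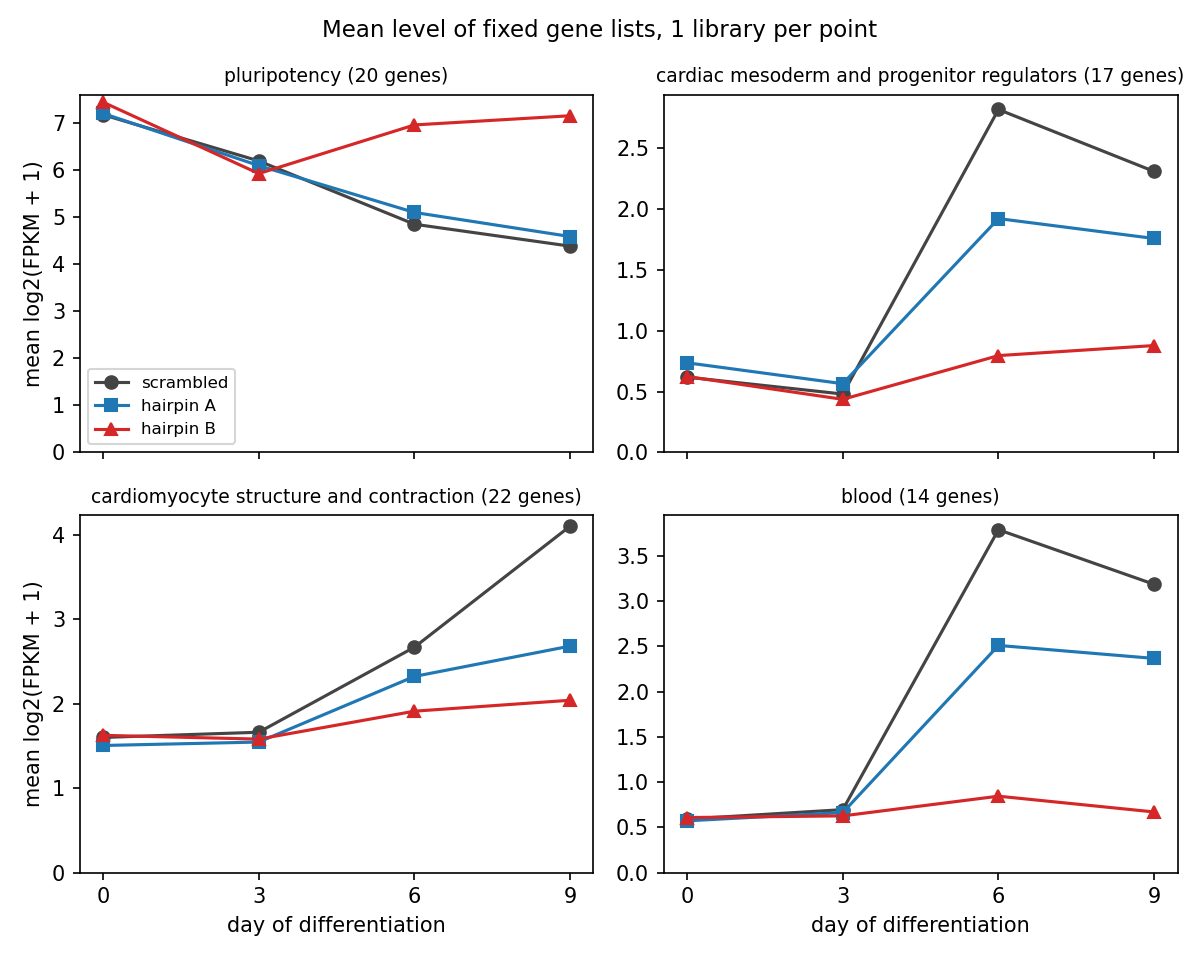
Mean log2(FPKM + 1) over the measured members of 4 fixed gene lists by day of differentiation, 1 library per point, with each vertical axis starting at 0. The pluripotency mean ends at 4.38 in the scrambled, 4.59 in the hairpin A and 7.15 in the hairpin B culture, while the cardiomyocyte, cardiac regulator and blood means are highest in the scrambled culture from day 6.

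By the size rule, 120 genes were at least 2-fold from the scrambled library in both hairpins at day 9 (27 higher and 93 lower), 146 at day 6 (50 and 96), 57 at day 3 (19 and 38) and 55 at day 0 (21 and 34). Without loci under 300 bp, day 9 gave 10 higher and 65 lower, day 6 gave 29 and 71, and days 3 and 0 gave 19 genes each. Tested for enrichment after these counts were seen, among the 13858 genes without those short loci, the 65 lower genes of day 9 held 11 of the 22 cardiomyocyte genes against 0.103 expected (Fisher's exact test, adjusted p = 1.55e-19), and 5 of 14 blood genes (adjusted p = 4.33e-08). The lower genes of day 6 held 8 of 14 blood genes (Fisher's exact test, adjusted p = 2.13e-14), and 6 of 17 cardiac regulators (adjusted p = 1.98e-09), Hand1, Hand2, Kdr, Mef2c, Pdgfra and Tbx1. Fisher's test takes the genes of a list as independent, and camera called none of these lists with an estimated correlation (adjusted p = 0.0666 and 0.516 for cardiomyocyte and blood genes at day 9, and 0.223 for blood genes and cardiac regulators at day 6). At day 9 hairpin B alone had 1911 genes at least 2-fold lower, against 165 in hairpin A, and its library lay near the early days. Genes that rise with differentiation can be lower there whatever their list, so Fisher's test does not show that the 2 hairpins agree. Both hairpins share the scrambled library, which makes them move together by chance. Unchanged groups simulated against a shared control gave 173.52 genes higher and 171.25 lower in both hairpins at day 9, more than observed. At day 0 they gave 172.87 and 173.7, where 21 and 34 were observed. The simulation took 1 spread per gene from the hairpin pairs of all days, with the distant hairpin B libraries of days 6 and 9 among them. It therefore cannot tell how many genes chance gives at day 9. Independent lists of each hairpin's genes would share 6.54 higher and 22.4 lower. With hairpin A taken as the odd library, 58 genes were higher and 32 lower in both others at day 9, and with hairpin B as the odd library 1504 and 1187.

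Most genes that passed limma's test of depletion were short RNA loci. At day 9 there were 5 (1 higher and 4 lower), against 199 genes at an unadjusted p under 0.05. Mir194-1 was listed at 0 in the scrambled library and read 331 and 203 FPKM with hairpins A and B, while Snord91a, Scarna17, Mir19a and Mir433 read 1577, 1559, 96.1 and 22.5 FPKM in the scrambled library and were listed at 0 in both hairpins. Day 6 gave 6 genes, day 3 gave 4, day 0 gave 3, and the mean over days gave 9, against 148, 37, 66 and 172 at an unadjusted p under 0.05. Those of day 3, all lower, were Snord91a, Snord111, Mir19a and Mirlet7i. With culture as a block, 3 of these 4 kept their call, and 6 of the 9 in the mean over days. Those of day 0 were Mir106b, listed at 0 in the scrambled library against 108 and 83.8 FPKM, and Snord111 and Mirlet7i, at 584 and 73.6 FPKM in the scrambled library and listed at 0 in both hairpins. At day 6 Snord1a was listed at 0 in the scrambled library and read 171 and 409 FPKM, and Scarna17, Mir106b, Mir19a and Mir433 read 412, 203, 102 and 52.8 FPKM there and were listed at 0 in both hairpins. With loci under 300 bp left out, limma called 0 genes in any of these comparisons. The reads behind the short loci are not known, since the time course gave no counts, and the libraries were made from mRNA. Values listed at 0 in both hairpins leave no spread between them, and Mir106b changed sides between days 0 and 6. The calls of short loci therefore do not show an effect of depletion. Leaving out a depleted library also took that day's hairpin pair out of the spread. The counts that follow can therefore change through the spread as well as through the effect. Leaving out hairpin A, the day 9 count became 157 and leaving out hairpin B 14. The mean over days became 24 without the day 9 library of hairpin A, 18 without that of hairpin B and 5 without the day 3 library of hairpin A. The day 0 count became 6 without hairpin A and 10 without hairpin B, the day 3 count 7 and the day 6 count 10 without hairpin A.

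The 10 measured genes flanking the Braveheart locus, among them Pdgfrb (8.92, 4.23 and 1.89 FPKM at day 9) and Camk2a (3.62, 1.10 and 1.11 FPKM), had a median of 0.22 and a mean of -0.13 at day 9, and camera gave an upward adjusted p of 0.752. Interferon response genes had a median of 0.45 at day 6, with 11 of 16 higher in both hairpins (camera adjusted p = 4.37e-05, and adjusted p = 0.176 with an estimated correlation). In that list the chemokine Cxcl10 read 0.991, 3.69 and 10.4 FPKM, and at day 9 the list median was 0.05 (adjusted p = 0.186). At day 9 the polycomb and DNA methylation list stood at 0.50 (adjusted p = 0.0017, and 0.516 with an estimated correlation), proliferation at 0.14 (adjusted p = 0.0226, and 0.548 with an estimated correlation) and Wnt targets at -0.58 (adjusted p = 0.0458, and 0.548 with an estimated correlation). These lay in the hairpin B library, with medians of 0.99, 0.25 and -1.23 there against 0.07, 0.00 and 0.08 in hairpin A. Without it camera called none of them (adjusted p = 0.33, 0.533 and 0.453). Camera made no call at day 9 for primitive streak (median -0.34, adjusted p = 0.415), epithelial (-0.13, 0.574), smooth muscle (-0.55, 0.274), skeletal muscle (0.04, 0.752), neural (-0.58, 0.106), p53 targets (0.44, 0.0587), amino acid and ER stress (-0.17, 0.352), hypoxia and glycolysis (0.15, 0.0791), BMP and TGFb targets (-0.51, 0.274) or long noncoding and imprinted RNA (-0.78, 0.153). At day 6, camera called 15 lists. Beside those above these were cardiomyocyte genes (median -0.14, adjusted p = 0.00724), skeletal muscle (1.16, 0.0334), proliferation (0.06, 0.0484), polycomb and DNA methylation (0.33, 0.0436), hypoxia and glycolysis (-0.28, 0.0439), Wnt targets (-0.80, 0.00605) and long noncoding and imprinted RNA (-0.54, 0.00159), none of them with an estimated correlation (adjusted p = 0.296 to 0.522). Without hairpin B the calls of proliferation, polycomb, Wnt and long noncoding lists were lost (adjusted p = 0.411, 0.697, 0.0962 and 0.129), and without hairpin A those of skeletal muscle and hypoxia (adjusted p = 0.106 and 0.161), although their means of 1.003 and -0.29 without it were no smaller than with it (0.70 and -0.24). The last list was primitive streak, with a median of -0.44 (adjusted p = 0.0183, and 0.509 with an estimated correlation), but without hairpin B its mean changed from -0.424 to 0.0750. At day 0, before differentiation, 12 of 16 hypoxia and glycolysis genes were lower in both hairpins, with a median of -0.46 (camera adjusted p = 5.89e-06, and adjusted p = 0.855 with an estimated correlation). The median was -0.18 in hairpin A and -0.82 in hairpin B, and the call was lost without the hairpin B library (adjusted p = 0.0561). The other list called at day 0 was amino acid and ER stress (median -0.25, adjusted p = 0.0269, and 0.731 with an estimated correlation), and this was lost without hairpin A (adjusted p = 0.198) with a mean of -0.22 against -0.23. Camera called no list at day 3.

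Over the 3 cultures, differentiation was under way by day 3. The ground-state pluripotency factor Klf4 fell from 125, 152 and 279 FPKM in the scrambled, hairpin A and hairpin B libraries of day 0 to 5.93, 6.36 and 4.28 FPKM at day 3, a log2 change of -4.76 ± 0.81 (SE, adjusted p = 0.0124). The epiblast growth factor Fgf5 rose from 5.38, 3.10 and 10.8 FPKM to 51.5, 32.7 and 46.4 FPKM, a change of 2.69 ± 0.49 (SE, adjusted p = 0.0169), and the de novo methyltransferase Dnmt3b rose by 2.10 ± 0.27 (SE, adjusted p = 0.00313). The kinase gene Pim2 rose by 2.75 ± 0.21 (SE, adjusted p = 0.00026) and the neural and epiblast factor Sox3 by 2.51 ± 0.26 (SE, adjusted p = 0.00126). Pou5f1 stayed high, at 788, 689 and 705 FPKM. Of 12 epithelial genes 4 rose, and 9 when adjusted over the list alone, with a median of 1.07 (camera adjusted p = 5.12e-06, and adjusted p = 0.246 with an estimated correlation). Fibroblast and extracellular matrix genes fell. In that list 10 of 20 fell, 14 when adjusted over the list alone, with a median of -1.30 (camera adjusted p = 3.24e-13, and adjusted p = 0.143 with an estimated correlation). The matrix crosslinking enzyme Lox fell from 13.997, 14.6 and 17.4 FPKM to 0.230, 0.172 and 0.229 FPKM, and S100a4 from 29.1, 34.3 and 26.5 FPKM to a listed 0 in all 3 cultures. Interferon response genes fell too, 9 of 16, or 12 when adjusted over the list alone, with a median of -1.46 (camera adjusted p = 1.92e-09, and adjusted p = 0.0331 with an estimated correlation). The ubiquitin-like modifier Isg15 went from 8.86, 9.16 and 16.8 FPKM to 0.849, 2.11 and 1.34 FPKM.

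At day 6 some genes of the primitive streak, endoderm and heart lists had risen over the cultures. The secreted antagonist Cer1 was listed at 0 in the scrambled and hairpin A libraries of day 0 and read 0.0507 FPKM with hairpin B, and at day 6 read 53.6, 69.7 and 10.7 FPKM (log2 change 5.13 ± 0.65 SE, adjusted p = 0.00385). The organizer gene Lhx1 rose by 3.51 ± 0.51 (SE, adjusted p = 0.00722) and Hand1 by 2.76 ± 0.61 (SE, adjusted p = 0.0283). The cardiac and endoderm factor Gata6 reached 10.7, 7.43 and 1.64 FPKM (adjusted p = 0.0314) and the endoderm factor Foxa2 32.8, 33.9 and 5.75 FPKM (adjusted p = 0.0418). Among 16 primitive streak genes 4 rose and 1 fell, or 8 and 1 when adjusted over the list alone, with a median of 0.93 (camera adjusted p = 0.00573, and adjusted p = 0.456 with an estimated correlation). Of 17 cardiac regulators 3 rose, or 9 when adjusted over the list alone, with a median of 1.02 (adjusted p = 0.00134, and 0.456 with an estimated correlation). Of 14 blood genes 2 rose, or 8 when adjusted over the list alone, with a median of 1.51 (adjusted p = 0.000541, and 0.456 with an estimated correlation). Pluripotency genes had a median of -1.81 (adjusted p = 0.000102, and 0.456 with an estimated correlation), with 1 of 20 past the threshold. The mesoderm factor T (brachyury) read 25.4, 51.1 and 6.01 FPKM and did not pass (adjusted p = 0.0748).

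By day 9 some contractile genes had risen over the cultures, with small values in hairpin B. Actc1 went from 0.597, 0.380 and 1.25 FPKM at day 0 to 140, 15.4 and 4.30 FPKM (log2 change 3.76 ± 0.84 SE, adjusted p = 0.0264), and Myl7 rose by 3.39 ± 0.91 (SE, adjusted p = 0.0393). Tnnt2 rose by 3.28 ± 0.75 (SE, adjusted p = 0.0277) and Tnni1 by 2.98 ± 0.78 (SE, adjusted p = 0.0381). Of 22 cardiomyocyte genes 8 rose and 1 fell, or 11 and 1 when adjusted over the list alone, with a median of 1.10 (camera adjusted p = 0.00706, and adjusted p = 0.625 with an estimated correlation). Pluripotency genes had a median of -1.95, with 3 of 20 falling, or 11 when adjusted over the list alone (adjusted p = 9e-07, and 0.625 with an estimated correlation). Klf2, another ground-state factor, fell by 3.49 on the log2 scale (± 1.00 SE, adjusted p = 0.0456), from 202, 172 and 564 FPKM to 9.77, 8.31 and 137 FPKM. The growth factor Igf2 rose by 4.59 ± 0.65 (SE, adjusted p = 0.00879) and the liver and yolk sac gene Afp by 2.72 ± 0.78 (SE, adjusted p = 0.0455). Interferon response genes stayed low, with 12 of 16 falling and a median of -1.50 (adjusted p = 3.81e-10, and 0.0245 with an estimated correlation). Proliferation genes had a median of -0.37, with 8 of 22 falling (adjusted p = 8.12e-06, and 0.625 with an estimated correlation). Myh6 (adjusted p = 0.0689), Pou5f1 (adjusted p = 0.052) and Nanog (adjusted p = 0.15) did not pass.

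In all, limma called 852 genes at day 3 against day 0 (460 higher and 392 lower), 1224 at day 6 (701 and 523) and 2337 at day 9 (1459 and 878). With culture as a block the counts were 1360, 2204 and 4218. They hung on single cultures: without hairpin B they were 4978, 7388 and 9095, without hairpin A 11, 9 and 10, and without the scrambled culture 16, 12 and 19. With no filter on low values day 9 gave 1709, and 7 of its 19 passing genes among the largest changes and the fixed lineage genes lost their call, Afp among them. P-values were then adjusted over more genes, and whether that was the cause was not tested. Median-ratio rescaling moved the split to 590 higher and 628 lower at day 6 and to 1067 and 1060 at day 9, where the median of all genes moved from 0.10 to 0.02.

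In the discovery set, mESC differed from MEF as pluripotent from mesenchymal cells do. Pou5f1, the core pluripotency factor, averaged 743 ± 75.7 CPM (SD, n = 4) in mESC against 0 counts in the MEF library, at least 1722-fold higher (edgeR, adjusted p = 0.001). Zfp42 (Rex1), a marker of naive stem cells, was at least 893-fold higher (adjusted p = 0.00121), Esrrb at least 592-fold (adjusted p = 0.00427) and Lin28a, a translational regulator, at least 365-fold (adjusted p = 0.00137). Nanog averaged 249 ± 37.7 CPM against 3 counts, or 0.431 CPM, in MEF (adjusted p = 0.00163). Of 20 pluripotency genes 17 rose, or 18 when adjusted over the list alone. Their median log2 difference was 12.75 as fitted and 8.23 with groups of 0 counts at the floor (camera adjusted p = 2.96e-17, and adjusted p = 0.0646 with an estimated correlation). Epithelial genes rose in 11 of 12, with a median of 10.71 (7.19 at the floor, camera adjusted p = 1.55e-10, and adjusted p = 0.0492 with an estimated correlation), and E-cadherin (Cdh1) averaged 604 ± 85.7 CPM against 0.144 CPM. All 21 fibroblast and matrix genes fell, with a median of -5.30 (camera adjusted p = 3.68e-22, and adjusted p = 0.0736 with an estimated correlation). The collagen Col1a1 averaged 267 ± 29.8 CPM against 36605 CPM in MEF, a log2 change of -7.10 (adjusted p = 0.0181), and the fibroblast surface marker Thy1 18.3 ± 4.89 CPM against 712 CPM (adjusted p = 0.00131). All 16 epithelial to mesenchymal transition genes fell (median -4.07, camera adjusted p = 1.51e-15, and adjusted p = 0.0492 with an estimated correlation), and all 9 smooth muscle genes (median -4.19, adjusted p = 7.99e-10, and 0.0492 with an estimated correlation). Proliferation genes rose in 18 of 22, or 20 when adjusted over the list alone, with a median of 2.00 (adjusted p = 5.46e-08, and 0.0492 with an estimated correlation). Polycomb and DNA methylation genes rose in 14 of 17 and fell in 1, with a median of 2.53 (adjusted p = 2.75e-07, and 0.0874 with an estimated correlation). The median of all genes in this comparison was 0.19 as fitted, 0.11 with median-ratio scaling and -0.30 on TPM.

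**Figure D4:**
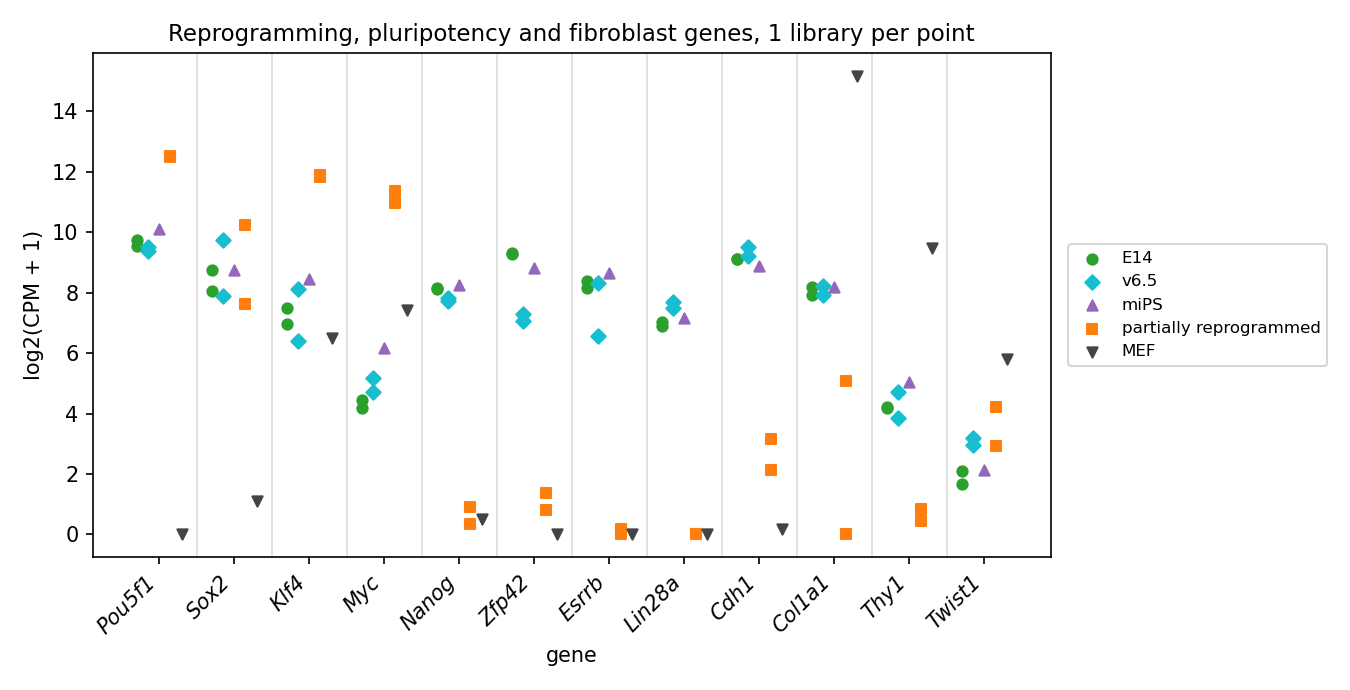
log2(CPM + 1) of reprogramming, pluripotency, epithelial and fibroblast genes in the 8 discovery libraries, 1 library per point and 1 marker per cell type. Partially reprogrammed lines have the highest Pou5f1 (5815 CPM on average against 743 CPM in mESC) with Nanog, Zfp42, Esrrb and Lin28a near 0, and MEF has the highest Col1a1 at 36605 CPM.

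The partially reprogrammed lines had more Pou5f1, Klf4 and Myc than mESC and less Nanog, Zfp42 and Lin28a. Pou5f1 averaged 5815 ± 58.2 CPM (SD, n = 2) there against 743 ± 75.7 CPM in mESC, a log2 difference of -2.97 for mESC (edgeR, adjusted p = 0.00108). Klf4 averaged 3667 ± 111 against 166 ± 83.8 CPM (-4.47, adjusted p = 0.0025) and Myc 2301 ± 463 against 24.5 ± 7.74 CPM (-6.59, adjusted p = 0.000595). Sox2 differed between the lines, at 1204 and 193 CPM, and its mean did not differ from mESC (adjusted p = 0.534). The counts cannot tell retroviral from endogenous transcripts. Nanog averaged 0.568 ± 0.430 CPM in these lines, 8.72 log2 units below mESC (adjusted p = 0.000851), and Zfp42 1.17 ± 0.591 CPM, 8.00 log2 units below (adjusted p = 0.000851). Lin28a had 0 counts in both lines and was at least 409-fold higher in mESC (adjusted p = 0.000851). Of 20 pluripotency genes 14 were higher and 2 lower in mESC, with a median of 7.16 as fitted and 6.27 at the floor (camera adjusted p = 4.68e-10, and adjusted p = 0.226 with an estimated correlation). Epithelial genes were higher in mESC in 10 of 12 (median 7.40, 6.36 at the floor, adjusted p = 2.56e-10, and 0.226 with an estimated correlation) and primitive streak genes in 8 of 11 (median 7.11, 3.49 at the floor, adjusted p = 2.64e-06, and 0.328 with an estimated correlation). Fibroblast and matrix genes were also higher in mESC, 12 of 21 against 1 lower, with a median of 3.38 (adjusted p = 7.21e-07, and 0.328 with an estimated correlation). In that list Col5a1 averaged 104 CPM against 2.60 CPM (5.31, adjusted p = 0.00231). Per the labels the mESC were grown on fibroblast feeders and the partially reprogrammed lines without them. The endothelial cadherin Cdh5 and the neural factor Zic1 were higher in the partially reprogrammed lines, at log2 differences of -8.43 (adjusted p = 0.003) and -6.08 for mESC.

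Against the MEF they came from, the partially reprogrammed lines had lost mesenchymal genes. In the fibroblast list 20 of 21 genes fell, with a median of -8.72 (camera adjusted p = 1.5e-32, and adjusted p = 0.0613 with an estimated correlation), and Col1a1 averaged 16.4 against 36605 CPM (edgeR, adjusted p = 0.0273). Smooth muscle genes fell in 8 of 9 (median -9.64, -8.14 at the floor, adjusted p = 1.52e-15, and 0.0441 with an estimated correlation). Epithelial to mesenchymal transition genes fell in 9 of 16, or 12 when adjusted over the list alone (median -2.78, adjusted p = 3.42e-13, and 0.0441 with an estimated correlation), while Twist1 did not pass (adjusted p = 0.0693). Proliferation genes rose in 13 of 22, or 18 when adjusted over the list alone, with a median of 1.82 (adjusted p = 1.17e-09, and 0.0441 with an estimated correlation). Pou5f1 was at least 13484-fold higher than in MEF (adjusted p = 0.000759), the amino acid transporter Slc38a5 at least 1241-fold (adjusted p = 0.00099) and Sall4 at least 125-fold (adjusted p = 0.0195). Of 20 pluripotency genes 8 rose and 2 fell (median 6.17, 1.36 at the floor, adjusted p = 0.000166, and 0.24 with an estimated correlation). Nanog read 0.568 against 0.431 CPM (adjusted p = 0.822), and Lin28a had 0 counts in both groups.

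Across genes, miPS correlated at 0.912 to 0.939 with the mESC libraries, at 0.844 and 0.850 with the partially reprogrammed lines and at 0.7704 with MEF. Pou5f1 read 1091 CPM against 743 ± 75.7 CPM (SD, n = 4) and Nanog 300.1 against 249 ± 37.7 CPM, and neither passed (edgeR, adjusted p = 0.663 and 0.839), which with 1 miPS library does not show that they were alike. Of 16773 genes, 5 passed and all were higher in miPS, against 1334 at an unadjusted p under 0.05 and 178 by DESeq2. They were Slc38a5 (14.6 CPM against 0.949 ± 0.0781, log2 3.93 ± 0.26 SE, adjusted p = 0.0304), the clone-named AL807811.1 (adjusted p = 0.0355), and the predicted genes Gm9761, Gm10071 and Gm15564, which were chosen after their values were seen (adjusted p = 0.0367, 0.0355 and 0.0208). Gm9761, Gm15564 and AL807811.1 also differed between E14 and v6.5 (adjusted p = 0.00925, 0.00438 and 0.0366), so these depend on the reference line, and their reads may be shared with near copies. Interferon response genes had a median of 0.95, with 0 past the threshold and 5 rising when adjusted over the list alone (camera adjusted p = 9.21e-06, and adjusted p = 0.161 with an estimated correlation). Epithelial and smooth muscle genes had medians of -0.96 and -1.50 (camera adjusted p = 1.19e-05 for each, and adjusted p = 0.161 with an estimated correlation). Primitive streak genes had a median of -0.55 (camera adjusted p = 0.000437, and adjusted p = 0.545 with an estimated correlation). For pluripotency genes it was 0.63 (camera adjusted p = 0.0103, and adjusted p = 0.545 with an estimated correlation). The count was 0 without either E14 library, 306 without v6.5 replicate 1, 53 without v6.5 replicate 2 and 1 without either partially reprogrammed library.

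The E14 and v6.5 lines differed in 82 genes (25 higher and 57 lower in E14). Zscan4c, of a gene family expressed in a small share of stem cells that resemble early cleavage embryos, averaged 27.4 ± 4.03 CPM (SD, n = 2) against 0.0996 CPM (edgeR, adjusted p = 0.0296) and Zscan4f was also higher in E14 (adjusted p = 0.0296), although reads of these near-identical genes are uncertain. Ftl2, a ferritin light chain copy, averaged 753 against 0.388 CPM (log2 11.06, adjusted p = 0.00925), and the ribosomal pseudogene Rpl23a-ps3 0.154 against 553 ± 555 CPM (-11.73, adjusted p = 0.033). Endoderm genes had a median of -1.74 in E14, with 0 past the threshold and 5 falling when adjusted over the list alone (camera adjusted p = 0.000552, and adjusted p = 0.326 with an estimated correlation). Epithelial genes had a median of -1.22 (adjusted p = 0.00217, and 0.326 with an estimated correlation). Pou5f1 averaged 790 against 695 CPM.

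For the checks below, the discovery libraries were taken as 2 sets, which no label gives and which were chosen after the data were seen. Both E14 libraries and v6.5 replicate 2 formed 1 set, and v6.5 replicate 1, MEF, the partially reprogrammed lines and miPS the other. Only v6.5 had a library in each, so set cannot be told apart from cell line for the others. In a fit of 1 set alone, the spread came only from the partially reprogrammed pair or the E14 pair. Counts from such fits can therefore change through the spread as well as through the set. The sets also differed in depth, with at least 12389911 reads per library in the first and at most 8762640 in the second. Across genes, v6.5 replicate 1 correlated at 0.897 with v6.5 replicate 2 and at 0.939 with miPS. Correlation did not give these sets by itself. miPS correlated at 0.912 to 0.932 with the first set and at 0.7704 with MEF. In all, edgeR called 4803 genes between mESC and MEF (2221 higher and 2582 lower), 4978 between mESC and partially reprogrammed (2702 and 2276) and 2318 between partially reprogrammed and MEF (830 and 1488). Within the set of v6.5 replicate 1 the counts were 585, 1168 and 1659, and 0 for miPS against mESC, where 178 were called by DESeq2 with all libraries. For E14 against v6.5, the set of v6.5 replicate 2 gave 4266. With the set as a term the counts were 5105, 4516, 4845, 0 and 603 in the order mESC against MEF, mESC against partially reprogrammed, partially reprogrammed against MEF, miPS against mESC and E14 against v6.5. Leaving out E14 replicate 1 or 2 gave 1639 or 1584 for mESC against MEF, 2047 or 1952 for mESC against partially reprogrammed and 944 or 962 for partially reprogrammed against MEF. Leaving out v6.5 replicate 1 or 2 gave 8453 or 7373, 8470 or 6945, and 4810 or 4837 in the same order. Leaving out a partially reprogrammed line gave 2181 or 2316 against mESC and 1241 or 1425 against MEF. The E14 against v6.5 count was 553 without v6.5 replicate 1, 4317 without replicate 2, and 0 without any 1 of the E14 or partially reprogrammed libraries.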

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

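The tests of less advanced differentiation, of loss of Braveheart, of a day 0 library grown like the other day 0 libraries (both days), of fibroblasts in the day 0 cultures, of sums over gene and pseudogene pairs and of GC content as the whole cause were chosen only after the results were seen.

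The depletion effect differed between day 9 and day 0 for 7 genes by limma's test of that difference, all of them loci under 300 bp. With culture as a block, 6 of the 7 kept their call. Snord111 (log2 difference 9.19 ± 0.36 SE, adjusted p = 0.000668), Mir194-1 (8.02 ± 0.50, adjusted p = 0.00403) and Mirlet7i (6.22 ± 0.37, adjusted p = 0.00403) were relatively higher with depletion at day 9. Scarna17 (-10.61 ± 0.36, adjusted p = 0.000504), Mir106b (-6.58 ± 0.40, adjusted p = 0.00403), Mir19a (-6.45 ± 0.31, adjusted p = 0.00153) and Mir433 (-4.55 ± 0.37, adjusted p = 0.0192) were relatively lower. Each rests on libraries listed at 0 beside libraries at 22.5 FPKM or more, as for Scarna17, listed at 0 in all 3 libraries of day 0 and in both hairpins at day 9 and at 1559 FPKM in the scrambled library of day 9. The count was 12 without the day 0 library of either hairpin, 36 without the day 9 library of hairpin A, 17 without that of hairpin B and 0 once loci under 300 bp were left out, against 157 genes at an unadjusted p under 0.05 with all loci.

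The hairpin B libraries of days 6 and 9 lay near those of early days, with a pluripotency list mean of 6.96 and 7.15 on the log2(FPKM + 1) scale against 7.44 at its day 0 and 5.92 at its day 3. Across genes, the library of day 9 correlated more with day 0 (0.944 to 0.953) than with day 3 (0.934 to 0.936), and that of day 6 more with day 3 (0.947 to 0.954) than with day 0 (0.934 to 0.945). The day 0 libraries correlated with one another at 0.957 to 0.967, above the values of the day 9 library with them, and its highest correlation was 0.957, with the day 6 library of hairpin B. In all, 104 genes were at least 4-fold from the nearest day 0 library at day 9 (852 in the scrambled and 764 in the hairpin A culture), against at most 81 between day 0 libraries. That ratio of 1.28 lies between the bounds set for and against a mislabelled day 0 library, so this stays open. At day 6 that ratio was 1.73 (140 genes). By a rule set after the results were seen, 47 genes at day 6 and 24 at day 9 were 4-fold from all 3 day 0 libraries. Each day 0 library set against the other pair gave 2, 2 and 12 genes, and the ratios to the highest were 3.92 and 2. These ratios argue against a library of cells grown like those of day 0, although they rest on only 3 reference values. Igf2 read 195 FPKM at day 9 of hairpin B, against at most 17.4 FPKM at day 0, and Cer1 10.7 FPKM at day 6. However, 17 of the 24 genes were lower, among them Lox and S100a4, so that an undifferentiated culture with fewer fibroblasts remains possible.

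Less advanced differentiation of the hairpin B culture may also give this pattern. However, its pluripotency list mean rose from 5.92 at day 3 to 6.96 and 7.15 at days 6 and 9. At day 3 the means of all cultures lay between 5.92 and 6.19. A slower course alone would not turn back, so these values argue against it for the pluripotency genes. For heart genes it stays open. The cardiac regulator and cardiomyocyte list means of hairpin B rose from 0.436 and 1.58 at day 3 to 0.878 and 2.04 at day 9. The changes from day 0 correlated across genes between hairpins B and A at 0.422, 0.434 and 0.171 at days 3, 6 and 9, and the last value lies between the bounds. Loss of Braveheart itself could not be tested, since its level was not analysed here. The pluripotency median of hairpin A over scrambled was 0.218 at day 9 and that of hairpin B 3.00. Heart genes below scrambled in hairpin A, as Actc1 at 15.4 against 140 FPKM, do not rest on the hairpin B library. That comparison has a single library on each side. On the first principal component hairpin A also lay below scrambled, at 45.3 against 53.3 at day 6 and 73.6 against 79.9 at day 9. Less advanced differentiation was not tested for hairpin A.

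Fibroblast transcripts were present in mESC and miPS. For 25 genes of at least 100 TPM in MEF and under 1 TPM in both partially reprogrammed lines, the mESC level had a median of 2.84% of that in MEF, and miPS 2.85%. Carry-over of the feeder cells named in the labels may be the source. It predicts alike percentages, and the third over the first quartile was 5.56, between the bounds of 3 and 10, so the test left it open. Col5a1 was at 1.57%, Col3a1 at 1.74% and H19 at 5.12% of MEF. In the time course, the lowest share over cultures of these genes that were more than 4-fold lower at day 3 than at day 0 was 28.6% (36.4% with hairpin B), below the 75% that fibroblasts lost from every culture would need. It met the bound against fibroblasts as first set (under 50%). That bound was replaced after the values were seen, because differentiating cells can turn these genes on again, and their median in the scrambled culture was 1.32 FPKM at day 3 and 7.35 FPKM at day 9. The replacement bound was the share among all genes, 3.49% with hairpin B, and with it the question stayed open. A biological explanation was not tested.

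Replicate 1 of v6.5 was nearer to miPS than to its own replicate. Members of 21 of 116 families of a gene and its pseudogenes lay apart between the library sets, against at most 16 in any other of the 56 splits. The sets were chosen after these same libraries were seen, so that rank is no independent support. Whether reads were assigned differently in part of the families stays open. For the 116 families together this is argued against, since sums over each gene and its pseudogenes kept 1.05 of the difference between the replicates. As the whole cause it is argued against too, since the correlation with replicate 2 stayed below that with miPS among other genes, by a difference of -0.0294. GC content or length may contribute. The difference between the v6.5 replicates correlated with GC content across genes at 0.579, and a fit on GC content and length moved the gap from -0.0507 to -0.0127. That value passed the bound of -0.01, but its interval over 1000 resamples of genes, -0.0175 to -0.00788, spans the bound, so a part played by GC content stays open. The upper end of -0.00788 lies below 0, which argues against GC content and length, as fitted, as the whole cause. A difference between library batches is in no label and cannot be separated from these.

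For the depletion effect averaged over days, 38 of the 81 ways to pick 1 library per day as the control gave at least the 9 genes of the real split, so chance is not excluded. The highest other split gave 6791 genes, with hairpin B as the control at days 0, 6 and 9, which points to a structure of the samples, the place of the hairpin B libraries. For the course of differentiation, the 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real split gave 852, 1224 and 2337 genes at days 3, 6 and 9, and the highest other 1, 1 and 33, with 1 split, the real one, at that size on each day.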

How the results depend on the processing

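The tests without loci under 300 bp, with DESeq2, with limma on TPM, with offsets for GC content and length, with the library set as a term, within one library set and without fibroblast genes were chosen after seeing the data. Of 1921 combinations of a named gene call and an alternative, 1662 kept their call and direction, 259 lost it and 0 reversed. Combinations in which the alternative did not test the gene are left out of these counts, so they overstate how often calls held. The short loci called for depletion are such a case when loci under 300 bp were dropped. Of 175 alternative values for counts and comparisons, 71 stayed within 1.5 times the main value. Where a cause is not given, the cause was not tested.

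With no filter on low values, limma called 14, 9, 26, 59, 63 and 47 genes for depletion at days 0, 3, 6 and 9, the mean over days and day 9 minus day 0. Without loci under 300 bp it called 0, 0, 0, 0, 0 and 0, since most passing genes were short, against 66, 37, 148, 199, 172 and 157 at an unadjusted p under 0.05 with all loci. Leaving out each depleted library gave 6 to 10, 4 to 7, 8 to 10, 14 to 157, 5 to 24 and 12 to 36 in the same order. Each of these fits also lost the hairpin pair of the day concerned from its spread. For genes 2-fold from scrambled in both hairpins at days 0, 3, 6 and 9, a pseudocount of 0.1 gave 134, 140, 390 and 260, and a 4-fold rule, stricter by construction, 28, 28, 39 and 40. Without loci under 300 bp these counts were 19, 19 and 75 at days 0, 3 and 9.

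Culture pairs the time course libraries, and with this replicate block the course of differentiation gave 1360, 2204 and 4218 genes at days 3, 6 and 9. Leaving out each culture gave 11 to 4978, 9 to 7388 and 10 to 9095. Of the 16, 17 and 19 genes past the threshold on these days among the largest changes and the fixed lineage genes, 6, 3 and 6 kept their call without the scrambled culture, 5, 3 and 3 without hairpin A and 14, 16 and 17 without hairpin B. With no filter on low values 16, 16 and 12 kept it, with all counts within 1.5 times (878, 1174 and 1709). In the discovery set, replicates share only a number (correlation of deviations 0.397 for the only pair checked), and a replicate block gave 29 genes for miPS against mESC. The block moved no other count of genes by more than 1.5 times. Among lists, camera with the block no longer called proliferation (adjusted p = 0.0603) and hypoxia and glycolysis (adjusted p = 0.0675) at day 6, and lost 2 of 12 lists in the mean over days, 1 of 7 at day 3 against day 0 and 2 of 8 for E14 against v6.5.

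DESeq2 called 178 genes for miPS against mESC and 1138 for E14 against v6.5, no filter 222 and 1417, and limma on TPM 34 and 3805, with 7924 for mESC against partially reprogrammed. With the library set as a term, edgeR called 0 genes for miPS against mESC (1334 at an unadjusted p under 0.05 without that term), 4845 for partially reprogrammed against MEF and 603 for E14 against v6.5. Within one library set the counts were 585 for mESC against MEF, 1168 for mESC against partially reprogrammed, 0 for miPS against mESC and 4266 for E14 against v6.5. The fits within 1 set took their spread from a single pair of libraries. Offsets for GC content and length gave 3595 for partially reprogrammed against MEF. Leaving out each replicate gave 1584 to 8453 for mESC against MEF, 1952 to 8470 for mESC against partially reprogrammed, 0 to 306 for miPS against mESC, 944 to 4837 for partially reprogrammed against MEF and 0 to 4317 for E14 against v6.5.

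With an estimated correlation in place of the preset one, camera's calls of lists went from 2, 15, 11, 12 and 12 to 0, 0, 0, 0 and 0 for depletion at days 0, 6 and 9, the mean over days and day 9 minus day 0. For the course they went from 7, 13 and 9 to 1, 1 and 1, all 3 being the interferon response list. They went from 11 to 4 for mESC against MEF, 12 to 0 for mESC against partially reprogrammed, 5 to 0 for miPS against mESC, 13 to 3 for partially reprogrammed against MEF and 8 to 0 for E14 against v6.5. Without the day 9 library of hairpin A, 11 of the 11 lists called at day 9 were kept, and without that of hairpin B 7. At day 6, 13 of 15 and 8 of 15 were kept. The mean of the primitive streak list at day 6 reversed from -0.424 to 0.0750 without the hairpin B library, and was -0.924 without that of hairpin A.

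A pseudocount of 0.1 and a choice among transcripts of a gene have no counterpart in the discovery count test, and the alternative for the level of Braveheart was not run. Depth limits low genes: 3 reads on a gene of 1 kb were 0.273 to 0.446 FPKM in the time course, above the 0.0378 FPKM of Hand2 with hairpin B at day 6.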

Other observations

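In the time course, genes of fibroblasts and of the interferon response fell between day 0 and day 3 in all 3 cultures. The mean of the interferon response list on the log2(FPKM + 1) scale went from 3.07, 3.02 and 3.23 in the scrambled, hairpin A and hairpin B cultures to 1.91, 2.07 and 1.83, and was 1.57, 1.64 and 1.77 at day 9. The fibroblast list went from 2.88, 3.03 and 3.01 to 1.24, 1.299 and 1.18, and was 3.14, 2.65 and 1.92 at day 9. Of the 25 genes used above as fibroblast transcripts, 20, 21 and 22 reached 1 FPKM at day 0. Their medians were 3.90, 3.86 and 4.68 FPKM at day 0 and 1.32, 1.72 and 1.29 FPKM at day 3. By day 3, 35.0%, 28.6% and 36.4% of them were more than 4-fold below day 0, against 2.76%, 2.66% and 3.49% of all genes.

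Zscan4c, of a family of near-identical genes whose reads are uncertain, read 20.0 to 40.2 FPKM at day 0, 0.463 FPKM at day 6 of hairpin B and 20.9 FPKM at its day 9.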
